A study of Caenorhabditis elegans with 2 samples.

How the data were processed

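ChIP-seq for a GFP and FLAG fusion of CEH-48 was done on whole late embryos of mixed sex from strain OP631, with chromatin sheared by sonication, per the labels. The labels' description states that a GFP antibody was used, while their antibody tag gives ceh-48. Both libraries are labelled as biological replicates of 1 group, so replicate numbers were taken from the labels and no comparison between groups was made.

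The region lists are in narrowPeak format, with a start, an end, a signal value, a −log10 q-value and a summit offset per region, for ce11 and for ce10. Per the deposited read-me files, the authors called peaks and background on each replicate's alignments and on both pooled, each with a further input file that is the same for all of them, and derived the IDR peaks from these lists. The signal of a region is the authors' deposited value from their peak caller; its scale is not stated, so it was used to describe and rank regions within a list. The −log10 q-value is likewise the authors' deposited value, is at its highest, 3.35, in 1117 of the 1840 IDR peaks, and was therefore not used for ranking. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The IDR peaks are the 1840 regions of the pooled list with the highest signal. Each replicate's list mixes peaks with background by its design, so its length is no count of binding sites. In the ce11 set, 8 IDR peaks repeat another peak's interval with a different summit, and each summit was counted. Read numbers are not in the region lists, so depth is unknown, and intervals cover counting of peaks or genes only.

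Chromosome names and coordinates of the ce11 lists were used with the WBcel235 reference sequence and the Ensembl release 115 annotation (19973 protein-coding genes and 612 tRNA genes on 6 nuclear chromosomes). The ce10 lists were used for counts and shares only, with no coordinate converted. A promoter window ran from 1000 bp upstream to 200 bp downstream of the 5′ end of a gene. A gene was bound when at least 1 IDR summit lay in its window. Places of summits were assigned in the order promoter, 5′ UTR, coding exon, 3′ UTR, intron and intergenic. Per-replicate values came from the 1840 regions of each replicate's own list with the highest signal. Summits within 100 bp were taken as the same.

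Shares of summits were tested against shares of nuclear bases with two-sided exact binomial tests, and windows or genes with two-sided Fisher's exact tests. Peaks that lie close together are not fully independent, and these p-values do not cover differences between embryo preparations. ATCGAT was searched in 100 bp centred on the summit and in windows of that size centred 500 bp to each side, and the same windows served for the scan of 2080 6-mers with strands collapsed. Genes were tested in 17 lists, with Benjamini-Hochberg adjustment over lists. The pan-neuronal list has 47 genes in the annotation, where nca-1 was not found, and the cut homeobox list has 5, without ceh-44. Some gene names occur more than once in the annotation, so the 72 histone and 1299 chemoreceptor genes carry 50 and 1289 names, and near-identical histone copies may share reads.

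The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes all cut homeobox genes, the genes at the 15 IDR summits with the highest signal where these lie in promoter windows (both genes between divergent 5′ ends, otherwise the nearest), the bound members of each list with the highest signal (up to 8 pan-neuronal and 4 of each other list), the first 6 unbound pan-neuronal genes in alphabetical order, and the 5 6-mers with the smallest p. Genes holding the top summits outside promoters, unc-80, rps-4 and the 6-mers GCGCGC and GCGCAC were named after their values were seen.

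Alternatives were the 920 IDR peaks with the highest signal, each replicate alone, other windows and flanks, the sequence ATYGAT (Y is C or T) on either strand, the ce10 lists, sub-threshold regions of the pooled list as background (27824 regions over 500 bp from an IDR summit), other rules joining summits to genes, and 10000 random gene lists matched on upstream intergenic length. Leaving out summits at tRNA genes was chosen after seeing the data, as was a separate count of the gene lists in sub-threshold regions. The tests were tried on simulated data: of 20 sets of 1840 random positions, 2 passed the promoter test, 0 the ATCGAT test, 1 had any 6-mer called and 0 had any gene list called at 0.05. A sequence planted in 10% of windows ranked first among 2080 6-mers in 20 of 20 sets, and a list given a summit at 30% of its 47 genes was called in 20 of 20. Positions not planted were uniform over the genome, whereas 51.2% of IDR summits lay in promoter windows. These rates therefore need not hold for summits with that bias. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.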

Results

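CEH-48 is a homeodomain protein of the ONECUT (cut) family that is made throughout the nervous system of the nematode Caenorhabditis elegans. The series holds 1 group of 2 biological replicates of chromatin immunoprecipitation with sequencing (ChIP-seq) from whole late embryos of strain OP631, collected 3.5 hours after synchronization. The worms carry a transgene that makes CEH-48 with GFP and FLAG at its C-terminal end, and the labels' description names an antibody against GFP, while their antibody tag names ceh-48. The data are ranked lists of regions with a summit and a signal value per region, in ce11 coordinates. Lists were given for each replicate, for both replicates pooled, and for the authors' reproducible peaks (IDR peaks). IDR is a test of how well ranks repeat between replicates. Here the IDR peaks are the regions of the pooled list with the highest signal. The replicate 1 list held 28372 regions and the replicate 2 list held 30000, and the pooled list held 30000. Read numbers are not given in the sources used here, so the depth of each library is unknown, and no other condition or untagged strain is analysed here. The design therefore asks where CEH-48 was found, how far both replicates gave the same regions, what sequence lay at the summits and which genes lay beside them.

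The IDR set held 1840 peaks, with signal values from 85.2 to 1044 and a median of 141. The peak with the highest signal lay on chromosome X from 4457956 to 4458306, 133 bp upstream of aps-2, which encodes the small subunit of a clathrin adaptor; its signal was 1044 in the pooled list, 315 in replicate 1 and 730 in replicate 2. The next peak, on chromosome III from 10759013 to 10759394 with signal 1038, lay between the divergent genes K01G5.10 and tasp-1. It was followed by a peak of signal 818 at ceh-38, another cut homeodomain gene, on chromosome II, and by a peak of signal 800 between C37A2.8 and E02D9.1 on chromosome I from 6799447 to 6799808. Among the 15 peaks with the highest signal, 7 lay in promoter windows, and the other 3 of these were at ZK643.2 and ZK643.5 (signal 702), nspc-17 (693) and unc-69 (691). A further 4 of the 15 were intergenic, 3 lay in introns, of nova-1, frm-7 and dys-1, and 1 lay in the 3′ UTR of H05C05.1. All 15 ranked 24th or better in replicate 1 and 18th or better in replicate 2.

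Among the 1840 regions of replicate 1 with the highest signal, 1245 had a summit within 100 bp among the top 1840 of replicate 2. The IDR peaks are the regions of highest signal in the pooled list, which was made from both replicates' alignments. Their presence in each replicate's list therefore lies above what unselected regions would give. How this choice moves the correlation below was not tested. Of the 1840 IDR peaks, 1737 had a summit within 100 bp in both replicates' lists, and across these peaks the signals correlated with Spearman's rho of 0.699 and Pearson's r of 0.733 on the log2 scale. These coefficients run across peaks, which are not independent replicates, so no p-value is given. Replicate 2 signals were higher by 1.44 ± 0.58 log2 units (SD over peaks), so signals are compared only within a list. Among the 1840 highest-ranked regions of its own list, replicate 2 held 1667 of the IDR peaks (90.6%, 95% exact binomial interval 89.2 to 91.9%) and replicate 1 held 1388 (75.4%, 73.4 to 77.4%). Both of these top lists held 1256 of the peaks, and 41 were in neither. The same further input is recorded for both replicates' lists, so part of their similarity may come from it.

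**Figure D1:**
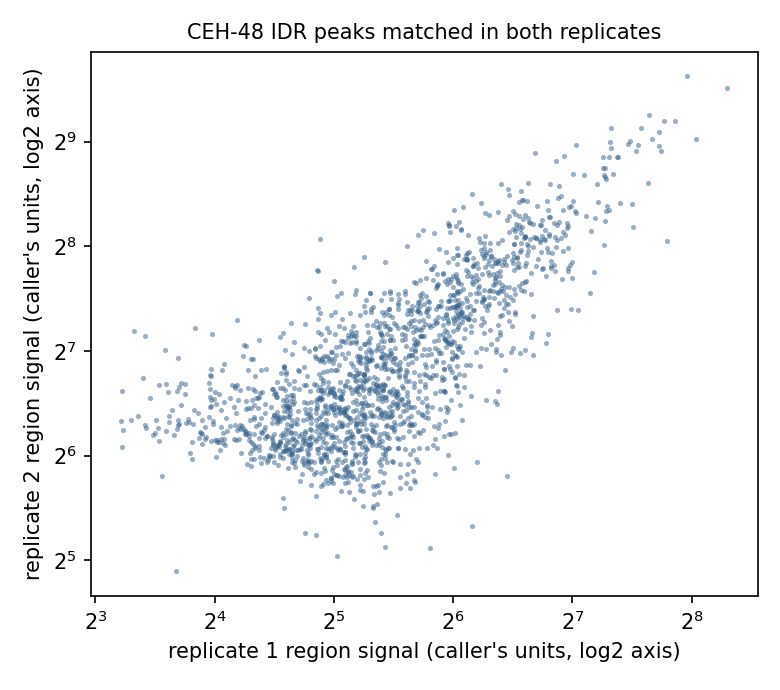
Each point is 1 of the 1737 IDR peaks with a summit within 100 bp in both replicates' lists, with its replicate 1 signal on the horizontal axis and its replicate 2 signal on the vertical axis, both in the caller's units on log2 axes. The 15 strongest peaks ranked 24th or better in both replicates. Of the 920 peaks with the highest signal, 896 were matched. The log2 difference between replicates had an SD of 0.48 over these against 0.58 over all of the matched peaks. Spearman's rho was no higher, at 0.694 against 0.699.

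CEH-48 summits lay at gene starts more often than bases do, and rarely in coding sequence. Promoter windows, from 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene, held 943 of 1840 summits (51.2%, 95% interval 48.9 to 53.6%) but 21.5% of nuclear bases, a 2.39-fold excess (two-sided exact binomial p = 7.26e-173). The share was 47.2% in the top regions of replicate 1 and 51.7% in those of replicate 2. Coding exons held 47 summits (2.55%) against 19.8% of bases (exact binomial adjusted p = 6.04e-111), introns held 479 (26% against 30.5%) and intergenic sequence held 327 (17.8% against 25%). The median summit lay 638 bp from the nearest 5′ end, compared with 1620 bp for random positions. Of the promoter summits, 318 lay in the windows of more than 1 gene, so 1256 genes had a summit in their window, 6.29% of the 19973 protein-coding genes. A window from 500 bp upstream to 100 bp downstream held 41.7% of summits, a 3.71-fold excess.

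The sequence ATCGAT, the core that cut homeodomain proteins bind in vitro, had the smallest p of all 2080 6-mers at CEH-48 summits. It occurred in the 100 bp around 814 of 1840 summits (44.2%, 95% interval 42 to 46.5%), against 337 of 3680 windows lying 500 bp to each side (9.16%), an odds ratio of 7.87 (two-sided Fisher's exact p = 1.73e-191). The odds ratio was 7.07 in the top regions of replicate 1 and 7.32 in those of replicate 2. ATCGAT was in 369 of 577 windows of summits at repeat-masked bases (63.95%, against 18.37% of their flanks). It was in 35.23% of the windows of the other 1263 summits. With tRNA genes left out, promoter summits had ATCGAT less often than other summits (39.5% against 57.6%). The splits by repeat and by promoter were made after the data were seen. The next 6-mers by p were parts or neighbours of the same core: TATCGA in 36.4% of summit windows against 9.48% of flanks, AATCGA in 45.1% against 15.2%, and CGATAA in 26.8% against 7.93%. The fifth, AAAATT, was less frequent at summits (24.6%) than in flanks (46.7%). With Benjamini-Hochberg adjustment of Fisher's exact tests, 620 6-mers were more frequent at summits and 539 less frequent (457 and 476 in replicate 1 alone, 645 and 566 in replicate 2 alone). By fold, ATCGAT (4.83) was below rarer 6-mers such as GCGCGC (7.21) and GCGCAC (6.68). Among the 922 peaks with ATCGAT within 100 bp of the summit, the nearest copy lay a median of 16 bp away, and 221 peaks had 2 or more copies in the 100 bp window. Stronger peaks carried it more often, at 241 of the 460 peaks with the highest signal (52.4%) against 176 of the 460 with the lowest (38.3%; odds ratio 1.78, Fisher's exact p = 2.18e-05).

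**Figure D2:**
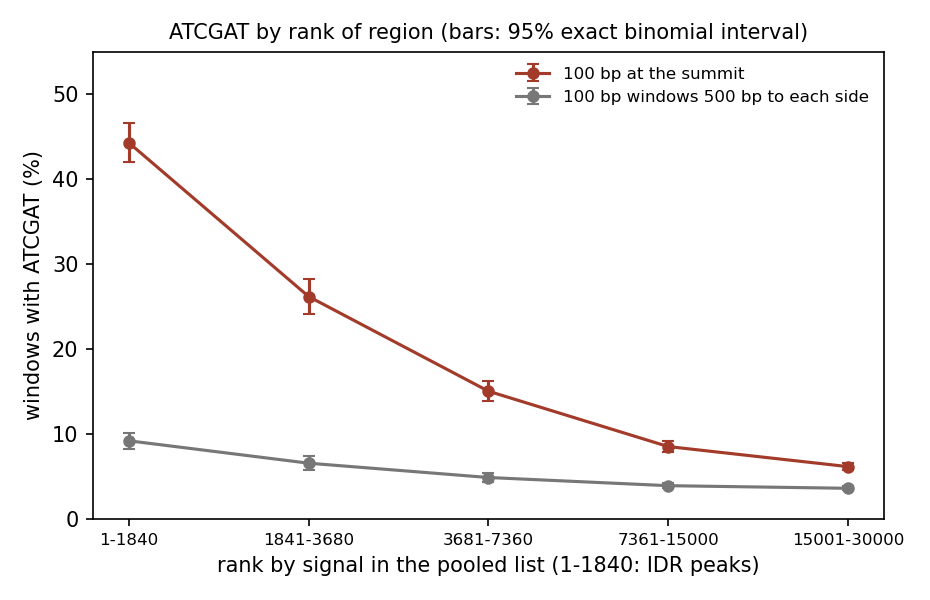
The vertical axis gives the percent of 100 bp windows with ATCGAT and the horizontal axis the rank of regions by signal in the pooled list, in 5 ranges of which the first is the IDR set; red points are windows at summits, grey points windows 500 bp to each side, and bars 95% exact binomial intervals. The share at summits was 44.2% in the IDR set and 6.12% at ranks 15001 to 30000, above the flanks in each range.

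Genes of the pan-neuronal list, meant to hold effectors that nearly all neurons use, were bound more often than other genes. Expression of its members was not checked here. CEH-48 had a summit in the promoter window of 14 of 47 pan-neuronal effector genes (29.8%, 95% interval 17.3 to 44.9%), against 6.23% of all other protein-coding genes (odds ratio 6.38, two-sided Fisher's exact test, adjusted over 17 lists p = 3.83e-06). The strongest was at unc-69, an axon outgrowth gene (signal 691; 214 in replicate 1 and 482 in replicate 2), on chromosome III from 10318852 to 10319171, 65 bp downstream of the 5′ end and also in the windows of unc-50 and ostf-4. It was followed by unc-16, a kinesin cargo adaptor (612), unc-18, a partner of syntaxin in vesicle fusion (444), rgef-1, a Ras exchange factor often used as a pan-neuronal marker (318), unc-14 (308), unc-11, a clathrin adaptor of synaptic vesicle recycling (285), ehs-1 (279) and ric-19 (222). All 14 of these peaks were among the top regions of replicate 1 and 13 among those of replicate 2, the exception being unc-80, which ranked 2277th there. Counted from each replicate alone, 16 and 13 of the 47 genes were bound in replicates 1 and 2. Such a rate was not particular to this list. Of 175 gene name classes tested after the data were seen, 16 were bound above other genes and 5 below. Those above included the vps (35.5%) and vha (35%) classes, which have no gene in the fixed lists.

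Among the 33 pan-neuronal genes with no summit in the window, several had one a little farther away. Of the first 6 in alphabetical order, egl-3, a neuropeptide-processing protease, had the 14th strongest peak of the set 1018 bp from its 5′ end (chromosome V from 10174616 to 10174943, signal 686), aex-3 had a summit at 1088 bp (125) and cpx-1 at 2424 bp (151). The nearest summits to casy-1, exc-7 and ida-1 lay 5802, 9749 and 14406 bp away. With each summit given to the nearest 5′ end at any distance, 32 of the 47 genes were bound (68.1% against 7.88%, odds ratio 24.9, Fisher's exact adjusted p = 1.28e-23). The count was 24 with windows of 2000 bp upstream to 500 bp downstream, and 24 with the gene body and 1000 bp upstream. The odds ratio was 10.5 with the 920 strongest peaks. Random lists matched on upstream intergenic length were run with the main window only. For the nearest 5′ end, the longer window and the gene body, upstream and gene length were therefore not controlled.

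Ribosomal protein genes were the other list bound above the rate of other genes, and chemoreceptor genes were bound below it. Summits lay in the windows of 29 of 76 ribosomal protein genes (38.2%, 95% interval 27.2 to 50%; odds ratio 9.39, Fisher's exact adjusted p = 4.17e-15), led by rpl-23 (signal 480), rpl-22 (447), rpl-3 (423) and rpl-41.2 (357). Replicates 1 and 2 gave 28 and 31 of these genes, and 20 of the 29 genes shared their summit with the window of another gene. Of 1299 chemoreceptor genes, 6 were bound (0.462% against 6.69%, odds ratio 0.0647, Fisher's exact adjusted p = 4.12e-28), with sre-23 (626), sri-5 (254), sre-1 (172) and srh-16 (170) the strongest. By nearest 5′ end at any distance, 18 ribosomal protein genes were bound (odds ratio 3.59, Fisher's exact adjusted p = 0.000137), and the chemoreceptor odds ratio was 0.117 (0.102 in the longest window). These 3 lists also passed against 10000 random lists matched on upstream intergenic length (permutation adjusted p = 0.00113 for each, adjusted from the smallest p these permutations can give), with the ribosomal fold at 4.12 against 6.19 over other genes. Regions below the IDR threshold lay in the windows of 44 ribosomal protein genes (57.9% against 30.2%), 124 chemoreceptor genes (9.55% against 31.8%) and 19 pan-neuronal genes (40.4% against 30.3%), with Fisher's exact adjusted p of 7.99e-06, 1.74e-75 and 0.298. Among these regions the axon guidance list (19 of 36) and the proteasome list (18 of 33) also passed above other genes, and nuclear receptors (57 of 269) below them. Regions within 500 bp of an IDR summit were left out here, so genes bound by an IDR peak had less of their window left to count. How far this lowered the pan-neuronal count was not tested.

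The other 14 lists did not pass. No gene of the neurotransmitter identity list (20 genes), the neuronal identity transcription factor list (37), the intestine list (20), the hypodermis list (32) or the germline list (29) had a summit in its window, which leaves shares of up to 16.8, 9.49, 16.8, 10.9 and 11.9% within the exact binomial intervals. The cilia list had 5 of 42 genes bound (11.9%, Fisher's exact adjusted p = 0.454), among them klp-11 and kap-1, which encode kinesin-II subunits (signals 366 and 126), daf-19, the RFX regulator of cilia genes (221), and dyf-3 (99.1). The axon guidance list had 3 of 36, namely unc-115 (440), the netrin receptor gene unc-40 (120) and the semaphorin gene mab-20 (100.4). Neuropeptide genes had 2 of 48, nlp-4 (203) and flp-23 (167), and the muscle list 1 of 39, unc-112 (86.9). The nuclear receptor list had 8 of 269 (2.97%, Fisher's exact adjusted p = 0.0933), led by nhr-49 (342), nhr-47 (309), nhr-1 (273) and nhr-255 (238). The proteasome list had 4 of 33 (rpn-7 162.8, rpn-2 104.04, rpn-11 99.1, rpn-3 91.1), the histone list 6 of 72 (his-72 230.3, his-35 and his-41 157 at a shared summit, his-37 129.6), and the ceh homeobox list 4 of 58 (ceh-88 311, ceh-86 153, ceh-89 105, ceh-100 97.7).

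**Figure D3:**
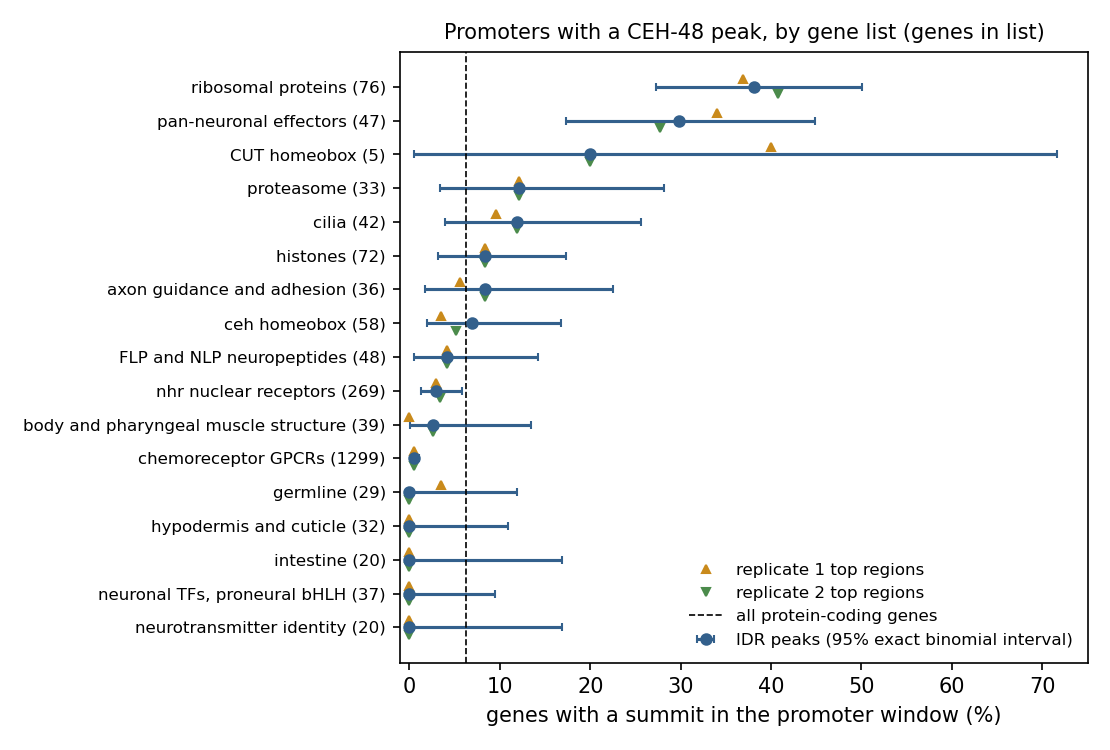
The horizontal axis gives the percent of genes of each list with a summit in the promoter window, with the number of genes in parentheses; blue points are IDR peaks with 95% exact binomial intervals, triangles the top regions of each replicate, and the dashed line all protein-coding genes (6.29%). Ribosomal proteins (38.2%) and pan-neuronal effectors (29.8%) have intervals wholly to the right of the line and lie there in both replicates, and the intervals of chemoreceptor genes (0.462%) and nuclear receptors (2.97%, not past 0.05 after adjustment over lists) lie wholly to its left.

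Of the cut homeodomain genes themselves, ceh-38 held the 3rd strongest IDR peak and ceh-48 held no IDR peak. The ceh-38 peak lay on chromosome II from 6951495 to 6951919, with its summit at 6951712, 186 bp inside the gene and just past the end of its first exon at 6951704, and also in the window of malt-1; its signal ranked 4th in replicate 1 (232) and 5th in replicate 2 (585), and 2 copies of ATCGAT lay within 100 bp around the summit. No IDR summit lay in the windows of ceh-21, ceh-39, ceh-41, ceh-44 or ceh-48, so 1 of the 5 genes in the main annotation was bound (Fisher's exact adjusted p = 0.471); the position of ceh-44 came from the RefSeq table. A region of the pooled list below the IDR threshold lay in the window of ceh-39 (signal 60.4, rank 3148) and another in that of ceh-21 (26.4, rank 19331). In replicate 1 alone, the ceh-39 region ranked 1717th, so 2 of the 5 genes were bound there (Fisher's exact adjusted p = 0.123). Within 20 kb of ceh-48, on chromosome IV from 6812108 to 6815607, there were 0 IDR summits against 0.798 expected (exact binomial p = 1). Replicate 1's top regions alone had 3 summits there (3.76-fold, exact binomial p = 0.0471), and those of replicate 2 had 0. Of these replicate 1 summits, 1 (rank 1426, signal 32.1) lay 265 bp downstream of the 5′ end of ceh-48, just outside the promoter window. The pooled and replicate 2 lists held no region at all within 20 kb, background included. The lack of an IDR peak at ceh-48 therefore does not show a lack of binding.

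**Figure D4:**
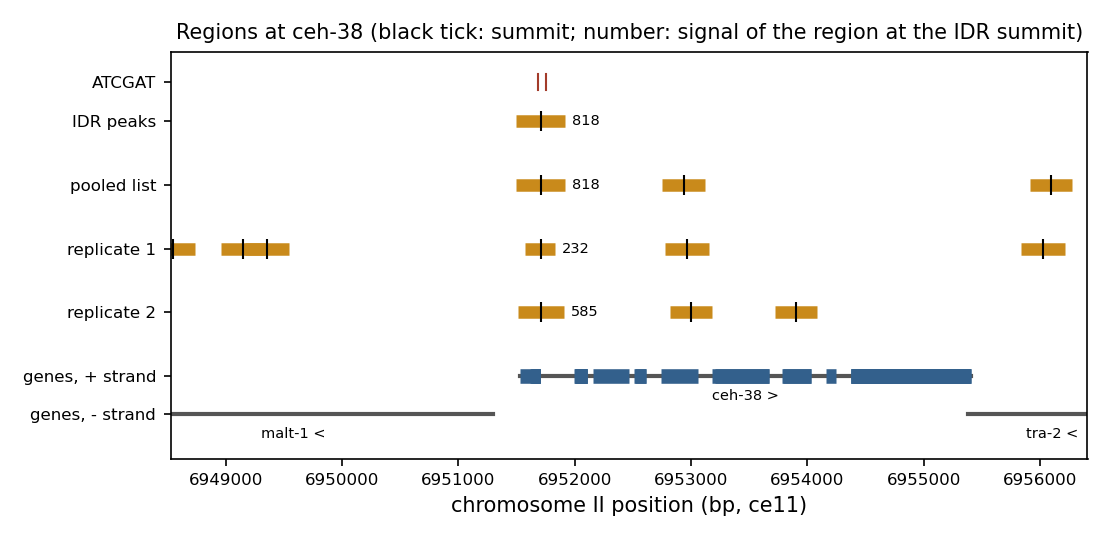
The map shows chromosome II positions in ce11 around ceh-38, with exons in blue, neighbouring genes as grey lines, regions of each list in orange with black ticks at their summits, and ATCGAT copies in red at the top. The region at the first exon and intron was found in each list, with signal 232 in replicate 1 and 585 in replicate 2.

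Summits were spread unevenly over the chromosomes. Chromosome I held 395 (21.5% against 15% of bases, exact binomial adjusted p = 6.57e-13) and chromosome III 365 (19.8% against 13.7%, adjusted p = 1.16e-12), while chromosome V held 242 (13.2% against 20.9%, adjusted p = 6.90e-17) and chromosome IV 266 (14.5% against 17.4%, adjusted p = 0.000966). Sub-threshold regions of the pooled list had shares of 19.4% on I, 18.8% on III, 16.3% on V and 13.9% on IV; the differences from these shares were not tested. The X chromosome held 308 (16.7% against 17.7% of bases, exact binomial p = 0.313); its share lay above that of sub-threshold regions of the pooled list (13.8%, odds ratio 1.25, Fisher's exact p = 0.000671) and of protein-coding genes (13.7%, exact binomial p = 0.000188), and below its share of bases in replicate 1 alone (14.7%, exact binomial p = 0.000771). On the autosomes, 653 of 1532 summits (42.6%) lay in the middle 50% of the chromosome, fewer than its share of bases (0.852-fold, exact binomial p = 8.48e-09). Against sub-threshold regions, of which 39.4% lay there, the direction was the opposite (odds ratio 1.14, Fisher's exact p = 0.0132).

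Transfer RNA genes, transcribed by RNA polymerase III, had many summits. Of the 1840 summits, 145 lay within 200 bp of a tRNA gene (7.88%), where 0.272% of bases lie, a 28.9-fold excess (exact binomial p = 1.17e-155), with 128 in the top regions of replicate 1 and 147 in those of replicate 2. These summits were at 155 of the 612 annotated tRNA genes, and ATCGAT was in the window of 3 of the 145 (2.07%). The excess was 14.4-fold within 500 bp, and the odds ratio against sub-threshold regions was 12.1.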

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

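Tests of sequence in sub-threshold regions, at tRNA genes and at ribosomal protein promoters, of masked repeats, of the regional background and of the gap length and the lost regions at ceh-48 were chosen after the result was seen. The design has 1 group, so no biological difference between groups was tested.

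Regions of the pooled list below the IDR threshold, which the report's peak set leaves out, still carried ATCGAT: 8.95% of their 27824 summit windows had it against 3.88% of flanks (odds ratio 2.43, Fisher's exact p = 6.75e-187). At ranks 1841 to 3680 the share was 26.1% against 6.52%.

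Peaks at tRNA genes and ribosomal protein promoters largely lacked the sequence found elsewhere. ATCGAT was in 2.07% of tRNA summit windows (95% interval 0.429 to 5.93%) against 47.8% of other summits and 1.72% of their own flanks. This argues against ATCGAT as the route to the tRNA group as a whole. At ribosomal protein summits ATCGAT was in 13.3% of windows (3.76 to 30.7%) against 40.4% of other promoter summits, tRNA genes left out. Their flanks had 3.33% (Fisher's exact p = 0.0926). With 30 windows, that comparison does not decide whether ATCGAT is the route to some of these promoters. At ribosomal protein promoters ATYGAT was above flanks (30% against 10%, Fisher's exact p = 0.0324), so a variant sequence at some of them stays open. At tRNA genes ATYGAT was in 4.14%, below the 10.7% of flanks. Of the 155 tRNA genes with a summit, 130 have an identical copy. Many tRNA windows are therefore not independent, which the tests and intervals for them do not cover. Signal at highly transcribed genes without the sequence predicts a share not above flanks, but recruitment of CEH-48 by other proteins would look alike. Transcription was not measured and an untagged control is not analysed here, so the share does not tell these apart. Reads shared between identical tRNA copies are argued against by the tRNA genes with no identical copy and none within 1000 bp, of which 18.8% had a summit (12 to 27.2%) against 0.875% of random windows and 27.7% of genes with a copy; near-identical copies were not tested.

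Autosomal summits lay in the arms more often than bases do. The pattern was in repeats: at unmasked bases 55.9% of summits lay in centres, where 55.6% of such bases lie (exact binomial p = 0.848), and at repeat-masked bases 18.3% did, against 40.4% of such bases (exact binomial p = 2.73e-28). The placing of masked bases as a whole is not enough, since summits at them lay in centres less often than such bases do. Repeats of particular kinds were not tested. A regional bias shared with sub-threshold regions, of which 39.4% lay in centres, stays open. The placing of ATCGAT alone is not enough, since 32.8% of summits with ATCGAT lay in centres against 39.3% of autosomal ATCGAT copies (exact binomial p = 0.000367). Reads shared between repeat copies were not tested.

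No region of the pooled or replicate 2 list lay within 20 kb of ceh-48, where 13.0 were expected in each list, while replicate 1 had 8 against 12.3 expected, with the strongest at rank 316 (summit 6809806, signal 73.6). The gap in the pooled list was 48685 bp, and 8.91% of the genome lies in gaps at least as long. Gaps of this length therefore occur elsewhere in this list. Random placement was not simulated, and observed gaps do not test it. Among the top 500 regions of replicate 1, 4 had no pooled or replicate 2 region within 500 bp, and 2 of these 4 were at ceh-48. With no pooled or replicate 2 region around ceh-48, any replicate 1 region there counts among them, so the count restates the gap. Loss of strong regions at the transgene's own locus was therefore not told apart from a gap of the kind seen elsewhere in the list.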

How the results depend on the processing

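Leaving out summits at tRNA genes was chosen after seeing the data; it was run for promoters, centres, ATCGAT, ATCGAT by signal and the gene lists, pan-neuronal included, and kept these 6 results' directions and calls. Promoter, tRNA and ATCGAT excesses, the higher ATCGAT share of stronger peaks and the pan-neuronal excess kept their direction and stayed past 0.05. This held in each alternative run on the IDR peaks and on the top regions of each replicate alone. In sub-threshold regions the pan-neuronal list did not pass. Those regions leave out any within 500 bp of an IDR summit, so that count does not retest the IDR peaks themselves. Among the results fixed for each comparison, 61 values under the other alternatives kept direction and call or, for counts, stayed within 1.5 times, 7 turned, 1 passed and 1 moved; among single lists and peaks 194 kept both, 13 turned, 2 passed and 6 peaks left a replicate's top regions. For each change below the cause was not tested. The fold of X summits over bases, 0.947, became 1.09 (not past 0.05) in the 920 strongest peaks, an odds ratio of 1.25 against sub-threshold regions, 1.22 against protein-coding genes, and 0.833 to 1.01 in single replicates, past 0.05 in replicate 1. Centres turned to an odds ratio of 1.14 against sub-threshold regions. At ceh-48 the fold was 1.05 within 50 kb and 0 to 3.76 in single replicates. The correlation of replicate signals was 0.732 with summits within 50 bp. Lists that did not pass changed side without passing: in the 920 strongest peaks neuropeptides had an odds ratio of 1.31, axon guidance 0.861 and proteasome 0.942; in single replicates ceh homeobox had 0.589 to 0.807 and axon guidance 0.972 to 1.35; the cut list had 0 in the shortest window; histones had 0.975 in the longest window, 0.673 by nearest 5′ end and 0.967 by gene body; neurotransmitter identity had 1.27 by nearest 5′ end; and against matched lists neuropeptides had a fold of 1.04 and histones 0.800. The number of lists that passed went from 3 to 4 where the nuclear receptor list passed, below other genes, in the longest window (odds ratio 0.454) and by gene body (0.450). Of the pan-neuronal, ribosomal and cut peaks, 43 of 44 were in the top regions of replicate 2 and 38 of 44 in those of replicate 1, where rps-4 had no region within 100 bp and so no value. No paired analysis was possible because there is 1 group. Depth is unknown, so weak binding cannot be excluded at any gene.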

Other observations

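The tests in this part were chosen after the data were seen.

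Gene name classes also differed. Among 175 classes of at least 10 protein-coding genes, 16 were bound above and 5 below the rate of other genes (Fisher's exact tests, Benjamini-Hochberg adjusted), of which 11 and 1 have no gene in the fixed lists. Vacuolar sorting genes (vps) had 11 of 31 bound (35.5% against 6.24%, adjusted p = 8.92e-05 in Fisher's exact test; 12 and 11 in replicates 1 and 2). Chaperone genes of the dnj class had 10 of 29, vacuolar ATPase genes (vha) 7 of 20, rab GTPase genes 7 of 20 and autophagy genes (atg) 5 of 12, the last with Fisher's exact adjusted p = 0.00716. The unc class, named for uncoordinated movement, had 17 of 94. The unc and rab classes share members with the pan-neuronal list. The other classes above were the ribosomal rpl and rps, lin (12 of 47), eif (8 of 25), sec (6 of 19) and npp (7 of 26). The last were cyn (5 of 16), gtf (4 of 10), taf (5 of 17) and sup (4 of 11). Classes were not tested against lists matched on upstream intergenic length. C-type lectin genes (clec) had 3 of 240 (1.25%, Fisher's exact adjusted p = 0.00357).

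The commonest 10-base sequence at summits was AAAATCGATA, in 416 of 1840 windows (22.6%) against 4.97% of flank windows. AAAATCAATA, whose other strand holds ATTGAT, was in 272 (14.8% against 3.12%).

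Bound pan-neuronal promoters may carry stronger peaks than other bound promoters. Their mean log2 signal was higher by 0.69 than at other promoter summits, tRNA genes left out (14 against 900 summits, permutation p = 0.00054). The median signal was 250.3 against 139. The difference was 0.75 in replicate 1 (permutation p = 0.00105) and 0.68 in replicate 2 (permutation p = 0.00086). Peaks at ribosomal protein promoters showed no such difference past 0.05 (0.18, permutation p = 0.178). ATCGAT was in 6 of the 14 pan-neuronal windows (42.9%) against 39.4% of these other promoter windows (Fisher's exact p = 0.79). ATYGAT was in 78.6% (95% interval 49.2 to 95.3%), an interval that includes the 60.3% of the other promoter windows.

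Another sequence at summits was GAGACGCAG, in 109 windows (5.92%) against 0.408% of flanks; it was put together from 6-mers enriched in these same windows, so that difference is no separate test. As a hypothesis, it marks summits that lack ATCGAT: it was in 7.50% of summits without ATCGAT and 3.93% of those with it (Fisher's exact p = 0.00137). Of summits with GAGACGCAG, 61.5% lay in promoters, against 50.6% of those without. Promoter summits had ATCGAT less often than others (39.5% against 57.6%, tRNA genes left out), so location was not separated from this contrast. GAGACGCAG was in 4 of the 14 pan-neuronal promoter windows (28.6%) against 7% of other promoter windows, tRNA genes left out (Fisher's exact p = 0.0151). In ribosomal protein windows it was in 1 of 30 (3.33% against 7.47% of other promoter windows, tRNA genes again left out, Fisher's exact p = 0.719). It was in 0 of the 145 tRNA windows, and an exact binomial interval that takes the windows as independent reaches 2.51%. Many are not independent, since 130 of the 155 tRNA genes at these summits have an identical copy. Which protein binds it was not tested.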
